A study of Mus musculus with 2 samples.

How the data were processed

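Gene expression was measured on single-channel oligonucleotide arrays in bone marrow cells of 6-week-old ddY mice, an outbred strain. Per the labels' protocols, mononuclear cells from a density gradient were stained for RANK, the receptor for the osteoclast differentiation factor RANKL, and for c-Fms, the receptor for M-CSF. They were then sorted by flow cytometry into a RANKhigh c-Fmslow and a RANKlow c-Fmshigh population. Total RNA was amplified into cDNA, and biotin-labelled sense-strand cDNA was hybridised. There was 1 array per population, 2 arrays in all, and the labels do not state how many mice each array represents.

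The deposited values are linear intensities, 1 per probe set and array. Per the submitters' processing notes, GCOS 1.4 and RMA were used. Their roles and order are not given in the sources used here. RMA itself returns log2 values, and how the deposited values came to be on the linear scale is likewise not given. Background correction and normalization between arrays were therefore those of the authors, and the scanner files were not used here. Intensities ran from 19.9 to 13198 on the RANKhigh c-Fmslow array, with a median of 94.5. On the RANKlow c-Fmshigh array they ran from 20.3 to 13453, with a median of 92.6. The analysis plan had assumed log2 values. The intensities were therefore put on the log2 scale first, with no pseudocount and no further scaling.

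Of 28815 probe sets, 21780 named 1 gene in the platform annotation of 2016, 1605 named several and were not used for genes, and 5430 were not listed in it. Entrez identifiers of 21689 of the 21780 were found in the reference gene table of the GRCm38.p6 assembly, and no symbol changed. Because the sources name no genome build for the array, no coordinates are given. Probe sets of the same gene were averaged on the log2 scale, which gave 19935 genes.

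The measure of each gene was its log2 intensity in RANKhigh c-Fmslow cells minus that in RANKlow c-Fmshigh cells. With 1 array per group there is no replicate error, so no test, p-value or standard error was computed. Genes were counted by size, at 2-fold or more (1 on the log2 scale), among the 11089 genes whose higher value reached 93.6, the median of all values of both arrays. Named in the text are the sort markers, the 12 genes with the largest difference in each direction among those 11089, and up to 4 members of each list with the largest absolute difference. Unnamed gene models, microRNAs, small nucleolar RNAs, chemoreceptors and immunoglobulin or T cell receptor segments were left out of the 12 and counted only. Genes named outside this rule are marked as chosen after their values were seen.

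Lists of 38 kinds (18 of cell type markers) were written before the data were examined, as were the size rule, the naming rule and the alternative settings. The lists have 557 entries, and 466 distinct genes of them were measured, 31 of which stand in more than 1 list. For each list the median difference was set against 10000 random lists of the same size, drawn from the other genes and matched on mean level in 20 bins. The percentile describes these arrays and is no p-value, because genes of a list vary together. By chance about 1.9 of 38 lists would fall outside the central 95% if genes varied independently.

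Expression of 1189 olfactory and vomeronasal receptor genes, which blood cells are not known to use as a class, served as a guide to background. Their median intensity was 35.4 and their 95th percentile 82.6. This guide was chosen after the data had been seen. Where a gene's lower value lay below the 95th percentile on its own array (83.8 on the RANKhigh c-Fmslow array, 81.8 on the other), its fold is a bound, the higher value over that percentile, written "at least". Ranks and counts use the measured values. No depth applies to arrays, and their number limits the precision. Of the genes with exactly 2 probe sets above the level filter (509 genes), the median gap between the 2 log2 differences was 0.19 and the 90th percentile 0.66. These figures cover disagreement within an array only.

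The size rule and the list percentiles were tested on simulated data with the real levels and normal noise of 2 sizes, the robust SD of the log2 differences over all 19935 genes (0.251) and over the 11089 genes that passed the level filter (0.405), on which the size rule runs. With the larger noise, simulated 4-fold changes were recovered in 98.5% of 66 genes, 2-fold changes, which lie on the threshold, in 65.7% of 67 genes and 1.5-fold changes in 16.4% of 67 genes, and of the 10889 unchanged genes 144 (1.32%) passed. With the smaller noise these shares were 100%, 53.7%, 5.97% and 0%. Both sizes hold real differences as well as noise, and without replicates the noise is not known, so the number of false calls among the genes at least 2-fold apart is not known either. A shift of all members by 0.5 placed 34 of 38 lists outside the central 95% with the larger noise and 38 of 38 with the smaller, against 3 and 0 lists without a shift. The noise was independent between genes, which real genes are not.

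The alternatives were centring each array on its median, quantile normalization, removal of the trend of the difference on level by loess (fraction 0.3), other level filters, thresholds of 1.5-fold and 4-fold, the highest probe set per gene, single probe sets, list means, filtered lists and unmatched random lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.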

Results

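The transcriptomes of a pair of sorted bone marrow populations were compared: cells with high RANK and low c-Fms on their surface, and cells with low RANK and high c-Fms. The study concerns osteoclast precursors, and both receptors act in osteoclast formation. Each population was measured on 1 array, so every value below is a single measurement with no replicate error, and no difference has a replicate check. The arrays are called the RANKhigh array and the c-Fmshigh array after their labels. Differences are log2 intensities on the RANKhigh array minus the c-Fmshigh array. Across probe sets, which are not independent replicates, the log2 intensities correlated with Pearson's r = 0.971.

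The transcripts of the sort markers were examined first, as a check of the labels. Csf1r, which encodes c-Fms, had an intensity of 164 on the RANKhigh array and 821 on the c-Fmshigh array, 5.02-fold lower in the former, in the direction of the label. Tnfrsf11a, which encodes RANK, did not show the direction of its label. Its intensity was 104 on the RANKhigh array and 119 on the c-Fmshigh array, a log2 difference of -0.20. Both values lay close to the median of all probe sets (94.5 and 92.6). They were above the 95th percentile of the olfactory and vomeronasal receptor genes on the same arrays (83.8 and 81.8), a guide to background. The name RANKhigh therefore refers to the sort label and not to the measured transcript.

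Over all genes, the RANKhigh array was higher in transcripts of granulocytes, B-lineage cells and erythroid cells, and the c-Fmshigh array in transcripts of monocytes. Of 11089 genes above the level filter, 481 (4.34%) were at least 2-fold higher on the RANKhigh array and 472 (4.26%) at least 2-fold higher on the c-Fmshigh array. By measured values, at least 8-fold differences were seen for 6 and 2 genes. These counts include Mgll and Met, for which only the smaller bounds given below can be stated. The largest excess on the RANKhigh array was that of Retnlg, a resistin-like protein made by marrow granulocytes, at 3059 against 177 (17.3-fold). Next came the eosinophil granule protein genes Prg3 (15.0-fold) and Prg2 (11.9-fold) and the eosinophil-associated ribonuclease gene Ear6 (12.8-fold). Ear6 belongs to a family of very similar genes that a probe set may not separate. Ly6g, the neutrophil surface antigen, was 10.1-fold higher and Lcn2, a siderophore-binding granule protein, 7.43-fold. The erythroid surface protein genes Icam4 and Rhd were 7.43-fold and 6.75-fold higher. The claudin gene Cldn13 was 7.55-fold and Nxpe2 7.13-fold higher. The monoglyceride lipase gene Mgll (617) and Lrg1 (452) were at least 7.55-fold and at least 5.52-fold higher, since their values on the c-Fmshigh array were not above the receptor genes.

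On the c-Fmshigh array the largest measured excess was that of Met, the hepatocyte growth factor receptor, at 512 against 56.4. The lower value was not above the receptor genes, so that Met was at least 6.12-fold higher. F13a1, the coagulation factor XIII A subunit made by monocytes, was 8.08-fold higher at 4177 against 517. Fn1, encoding fibronectin, was 6.34-fold higher at 4187 against 661. The lipid transporter gene Abca9 was 7.49-fold higher, and the integrin gene Itga1, not above the receptor genes on the RANKhigh array, at least 6.27-fold. Gria3, a subunit of the AMPA glutamate receptor, stood at 2466 against 342 (7.20-fold), and Il6st, the shared signalling receptor of the interleukin-6 family, at 2513 against 385 (6.53-fold). Ms4a6d (6.84-fold), Tgfbi (6.40-fold), Vwa5a (6.35-fold), Stxbp6 (6.24-fold) and the C-type lectin gene Clec4a1 (6.24-fold) completed the 12. Of the gene kinds left out of these sets, 20 were at least 2-fold higher on the RANKhigh array, 5 of them immunoglobulin or T cell receptor segments. On the c-Fmshigh array 15 were, with 0 segments among them.

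**Figure D1:**
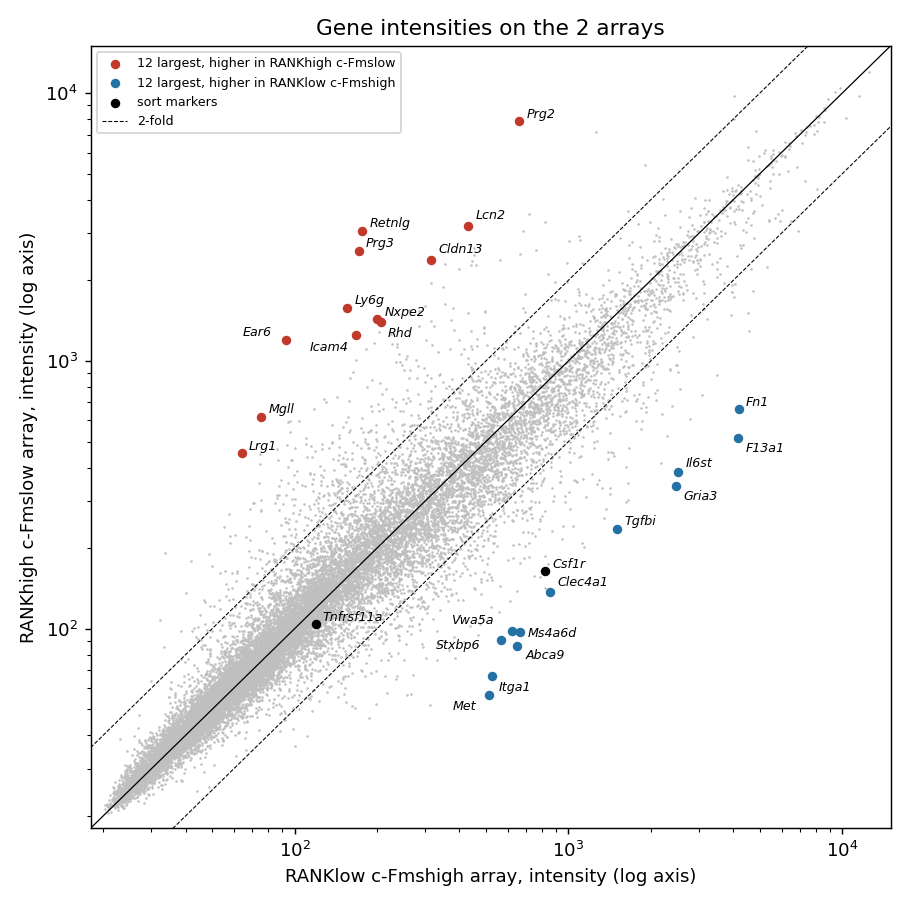
Intensity of each gene on the c-Fmshigh array (x axis) and on the RANKhigh array (y axis), both on log axes, with 1 array per group; the solid line marks equal values and the dashed lines 2-fold. Retnlg lies at 3059 against 177, Met at 56.4 against 512, and Tnfrsf11a (104 against 119) lies near the line of equal values while Csf1r (164 against 821) lies below it.

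Monocyte markers were higher on the c-Fmshigh array. All 11 measured markers were lower on the RANKhigh array, 5 of them at least 2-fold, and the median log2 difference was -0.97, below every matched random list (percentile 0). Beside F13a1 and Fn1 these included Ccr2, the receptor that brings monocytes out of the marrow (607 against 2771, 4.57-fold), and Ms4a6c (3.94-fold). The macrophage list was divided, with 3 members at least 2-fold lower on the RANKhigh array, 2 at least 2-fold higher and 10 in between (percentile 55.8). The scavenger receptor gene Msr1 (5.34-fold), Adgre1, which encodes F4/80 (3.25-fold), and Cd68 (2.67-fold) were lower on the RANKhigh array, whereas the complement gene C1qc was higher at 457 against 152. Among 12 dendritic cell markers 3 were at least 2-fold lower on the RANKhigh array and 2 at least 2-fold higher, with a median of -0.56 (percentile 0). Sirpa was 2.47-fold lower there. Cd209a and Clec9a, whose values on that array were not above the receptor genes, were at least 3.97-fold and at least 1.63-fold lower. Ccr7, which lymphocytes also use, was 2.49-fold higher.

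Granulocyte markers were higher on the RANKhigh array. The cells came from the mononuclear layer of a density gradient, a step that depletes mature granulocytes. Of 15 neutrophil markers, 9 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 1.28 (percentile 100). The 3 members below 0, by less than 2-fold, were genes of the primary granules, which form early in neutrophil development. The list was led by Retnlg, Ly6g, Lcn2 and Cxcr2, the chemokine receptor of mature neutrophils (1113 against 182, 6.11-fold). Eosinophil markers had a median of 1.86 (percentile 100), with 6 of 8 at least 2-fold higher, and Epx, the eosinophil peroxidase gene, was at least 3.37-fold higher beside Prg3, Ear6 and Prg2. Of 12 basophil and mast cell markers 5 were at least 2-fold higher, with a median of 0.72 (percentile 100). Over the 7 members that passed the level filter the median was 1.56. The basophil protease gene Mcpt8 stood at 1957 against 316 (6.20-fold) and Prss34 at 545 against 185 (2.95-fold). Cpa3 was at least 2.71-fold and Fcer1a, a chain of the IgE receptor, at least 2.10-fold higher.

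B-lineage transcripts of early and later stages were both higher on the RANKhigh array. Of 13 early B cell markers 11 were at least 2-fold higher, with a median of 1.64 (percentile 100). Pax5, the transcription factor of B-lineage commitment, stood at 1544 against 262 (5.89-fold), the surrogate light chain partner Vpreb3 was 5.40-fold, the adaptor Blnk 4.74-fold and Dntt, terminal transferase, 3.89-fold higher. Of 10 mature B cell markers 9 were at least 2-fold higher, with a median of 1.82 (percentile 100). Fcer2a, which encodes CD23, was 5.18-fold higher, Ms4a1, which encodes CD20, 4.47-fold, Fcmr 4.08-fold and Bank1 3.83-fold. Of 9 plasma cell markers 3 were at least 2-fold higher, Jchain (2.46-fold), Mzb1 (2.29-fold) and Irf4 (2.18-fold), and the median of 0.25 lay inside the central range of random lists matched on level (percentile 97.2) but outside it when they were not matched (98.59). Prdm1 was at least 1.84-fold lower.

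T and NK cell markers were also higher. Of 13 T cell markers 3 were at least 2-fold higher on the RANKhigh array and 10 lay in between, with a median of 0.37 (percentile 99.96), or 0.67 over the 9 that passed the level filter. The CD3 chain genes Cd3d (6.16-fold) and Cd3g (3.94-fold) and the adaptor Lat (2.10-fold) were the 3. Of 12 NK cell markers 3 were at least 2-fold higher, namely Gzma (2.88-fold), Nkg7 (2.69-fold) and Klrd1 (2.57-fold), with a median of 0.69 (percentile 100), or 1.01 over the 6 that passed the level filter. For 6 of those 12 NK cell markers both values lay below the pooled 95th percentile of the receptor genes (82.6). Plasmacytoid dendritic cell markers had a median of 0.47 (percentile 99.91). Spib (3.75-fold) and Ly6d (3.64-fold), which B-lineage cells also express, and Cox6a2 (2.66-fold) were higher, and Pld4 was 2.30-fold lower.

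All 11 measured erythroid markers were at least 2-fold higher on the RANKhigh array. Over all measured members this was the highest list median of all (2.01, percentile 100). By list mean the eosinophil list was higher (2.10 against 1.92). The Rh-associated glycoprotein gene Rhag stood at 1164 against 196 (5.95-fold), Ermap at 1888 against 347 (5.44-fold), the anion exchanger gene Slc4a1 at 2370 against 444 (5.34-fold) and Epb42, a membrane skeleton gene, at 1154 against 227 (5.08-fold). Of 8 megakaryocyte and platelet markers 1 passed 2-fold, platelet factor Pf4 at 959 against 283 (3.39-fold), with a list median of 0.49 (percentile 99.83). Among 13 stem and early progenitor markers Slamf1 was at least 2.16-fold higher and Cd34 2.18-fold lower, and 11 lay in between (median 0.29, percentile 99.62). None of the 13 osteoblast and stromal or 11 endothelial markers reached 2-fold, with medians of -0.03 (percentile 15.8) and 0.10 (percentile 84.3). The endothelial median was 0.20 over the 3 members that passed the level filter. In these lists the largest differences were those of the chemokine gene Cxcl12 (-0.37) and of Pecam1 (0.54).

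**Figure D2:**
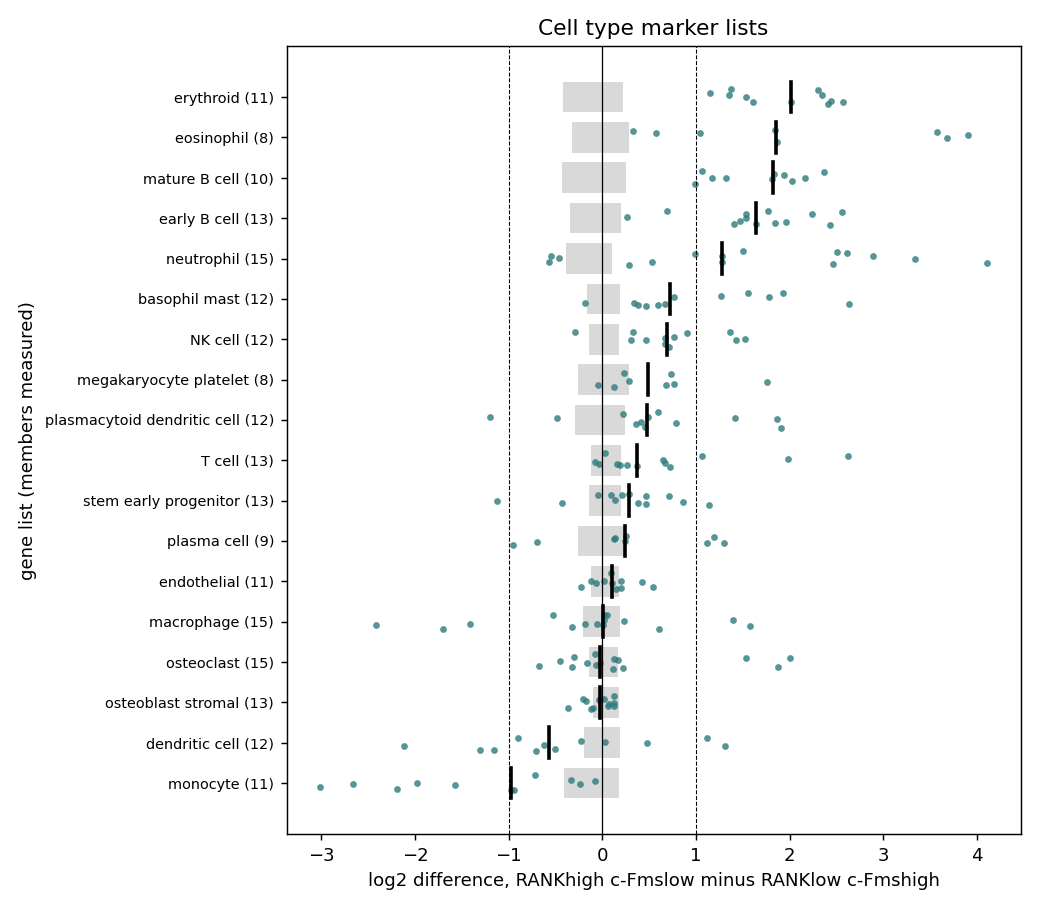
Log2 difference (x axis) of each measured member (points, spread vertically to separate them) of the 18 cell type marker lists (y axis); black bars are list medians, grey boxes the central 95% of matched random list medians and dashed lines 2-fold. Erythroid (2.01), eosinophil (1.86) and B cell medians lie at the right and the monocyte median (-0.97) at the left, while the osteoclast median (-0.03) lies inside its grey box.

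The osteoclast list addressed the subject of the study most directly. Of its 15 genes, 3 were at least 2-fold higher on the RANKhigh array, 0 at least 2-fold lower and 12 in between; the median was -0.03 (percentile 31.7) and the mean 0.26, and over the 9 members that passed the level filter the median was 0.12. Car2, carbonic anhydrase II, stood at 3300.1 against 824 (4.01-fold), Mmp9, a gelatinase, at 277 against 75.2 (at least 3.38-fold) and Acp5, tartrate-resistant acid phosphatase, at 546 against 188 (2.90-fold). Car2 is also abundant in erythroid cells and Mmp9 in neutrophils, whose marker lists had medians of 2.01 and 1.28. Which cells carried the Car2, Mmp9 and Acp5 transcripts was not tested. The integrin gene Itgb3 was 1.59-fold lower. Of the 15 genes, 10 were above the 95th percentile of the receptor genes (82.6) on at least 1 array, among them Tcirg1 (327 against 367), Ostm1 (221 against 301), Clcn7 (98.1 against 123) and Ocstamp (86.8 against 88.5). Others were low on both arrays: Ctsk, cathepsin K, stood at 59.7 against 73.8, the calcitonin receptor gene Calcr at 51.9 against 54.8, the fusion gene Dcstamp at 50.7 against 53.2 and the proton pump subunit gene Atp6v0d2 at 37.1 against 33.1. These last 4 genes lay below the 95th percentile of the receptor genes (82.6) on both arrays, so neither detection nor a difference can be stated for them. Both sets of 4 genes were chosen after their values were seen. Nfatc1, also chosen in that way, the transcription factor induced by RANK signalling, stood at 192 against 176.

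**Figure D3:**
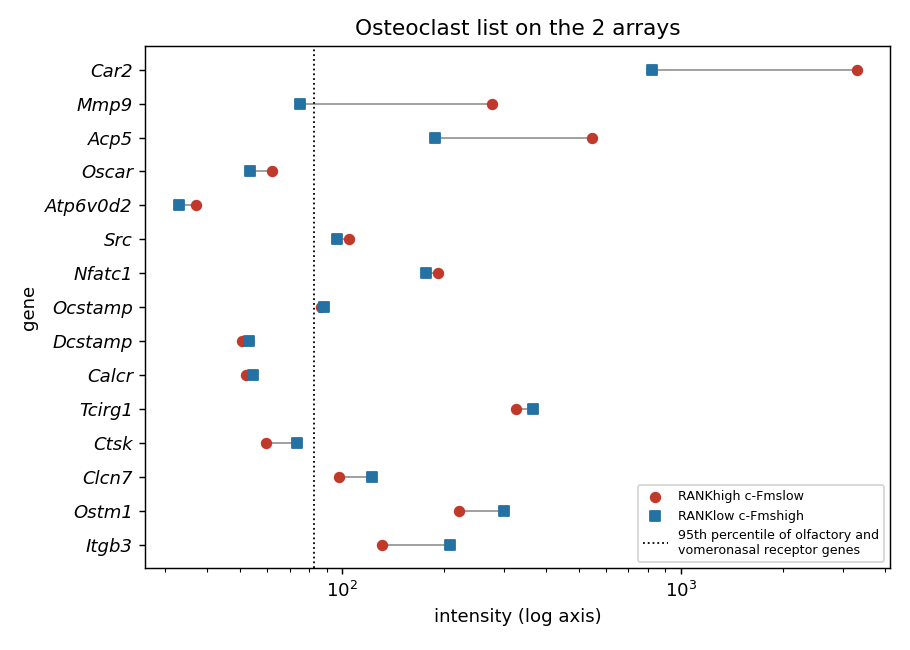
Intensity (x axis, log) of the 15 genes of the osteoclast list (y axis) on the RANKhigh array (circles) and the c-Fmshigh array (squares), 1 array each; the dotted line is the 95th percentile of the olfactory and vomeronasal receptor genes (82.6). Car2, Mmp9 and Acp5 are the 3 genes with wide gaps, and Ctsk, Calcr, Dcstamp and Atp6v0d2 lie left of the dotted line on both arrays.

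Lists of signalling and regulator genes related to the receptors were compared next. Of 15 RANK signalling genes 0 were at least 2-fold higher and 1, the adaptor Gab2, was at least 2-fold lower on the RANKhigh array (2.04-fold), with a median of 0.01 and a mean of -0.13 (percentile of the median 53.8). The kinase gene Ikbkb (-0.99) and Traf6 (-0.57) were also lower, and Relb stood at 108 against 73.1, the latter not above the receptor genes. Among 14 transcription regulators of osteoclast formation, 1 was at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.54 (percentile 0.02). Tfec stood at 403 against 1618 (4.02-fold lower), and Spi1, which encodes PU.1 (-0.99), and Irf8 (-0.95) lay just inside 2-fold. Monocytes use several of these genes, and the monocyte list, which also holds Irf8, had a median of -0.97. The regulator list was not divided into genes that promote and genes that repress osteoclast formation. Its median therefore gives no direction for that process. The list of c-Fms signalling genes, which holds Csf1r itself, had a median of -0.36 (percentile 2.08). Gab2, Cbl (1.99-fold) and Csf2rb (-0.87) were lowest after Csf1r. This list also holds receptor chain genes of other cytokines, Csf2rb among them, so its median does not describe c-Fms signalling alone. Without Csf1r its median was -0.34 and it no longer lay outside the central range (percentile 3.56). Of 11 genes of ITAM-dependent costimulation, Blnk was 4.74-fold higher, Fcer1g 2.01-fold lower and Tyrobp (-0.72) lower, around a median of 0.01 (percentile 69.3).

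Endolysosomal, adhesion and glycolytic genes were higher on the c-Fmshigh array, together with the monocyte markers. Of 14 lysosome genes 7 were at least 2-fold lower on the RANKhigh array and 0 at least 2-fold higher, with a median of -0.98 (percentile 0). Psap, prosaposin, stood at 1509 against 4529, and Hexa (2.99-fold), Lamp1 (2.94-fold) and Npc2 (2.70-fold) followed. Subunits of the V-ATPase, the proton pump of lysosomes and of the osteoclast's resorbing membrane, had a median of -0.37 (percentile 1.53). Atp6v1a (2.81-fold) and Atp6v1b2 (2.33-fold) were at least 2-fold lower, and Atp6v0a1 was 1.93-fold higher. Of 16 integrin and adhesion genes 13 were lower, 2 of them at least 2-fold, Selplg, a selectin ligand (2.86-fold), and Cd44 (2.61-fold), with a median of -0.64 (percentile 0). Glycolysis genes had a median of -0.63 (percentile 0.16), with Pgam1 (2.38-fold), Hk2 (2.05-fold) and Pkm (2.01-fold) at least 2-fold lower.

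The list of chemokine receptors also holds sphingosine 1-phosphate receptors, S1pr1 among them. Its members differed in both directions, with 5 of 17 at least 2-fold higher and 3 at least 2-fold lower on the RANKhigh array (median 0.27, percentile 99.89). Cxcr2 (6.11-fold) and S1pr1, the sphingosine 1-phosphate receptor of lymphocyte egress (3.20-fold), were higher. Ccr2 (4.57-fold) and Cx3cr1, a receptor of circulating monocytes (2.96-fold), were lower. Of 8 MHC class II genes 3 were at least 2-fold higher, H2-Oa (2.26-fold), H2-Ab1 (2.06-fold) and H2-Ob (2.02-fold), and H2-DMa was 2.05-fold lower (median 0.87, percentile 99.99), beside a mature B cell median of 1.82. Interferon-stimulated genes had a median of -0.45 (percentile 0.1) and a mean of -0.17, with Mx1 (2.89-fold) and Oasl2 (2.37-fold) lower and Isg20 (4.73-fold) and Rsad2 (2.14-fold) higher. The list of Toll-like receptors and cytokines lay inside the central range (median -0.13, percentile 10.3, and -0.27 over members that passed the level filter), with Tlr8 (at least 3.18-fold) and Tlr7 (at least 1.79-fold) lower and Il1b (2.16-fold) higher.

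Proliferation genes were expressed on both arrays and differed little. All 19 measured mitotic cell cycle genes were higher on the RANKhigh array, 0 of them by 2-fold, with a median of 0.31 (percentile 99.97). Mki67, the Ki-67 antigen, stood at 3308 against 1982 (1.67-fold) and Ube2c at 712 against 422 (1.69-fold). The 18 DNA replication genes had a median of 0.11 (percentile 96.0), from Mcm3 (-0.63) to the cyclin gene Ccne1 (0.82). Cell cycle inhibitor genes had a median of 0.30 (percentile 99.68), and Gadd45a was the 1 of 13 at least 2-fold higher (2.69-fold), followed by Cdkn2c (0.89).

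**Figure D4:**
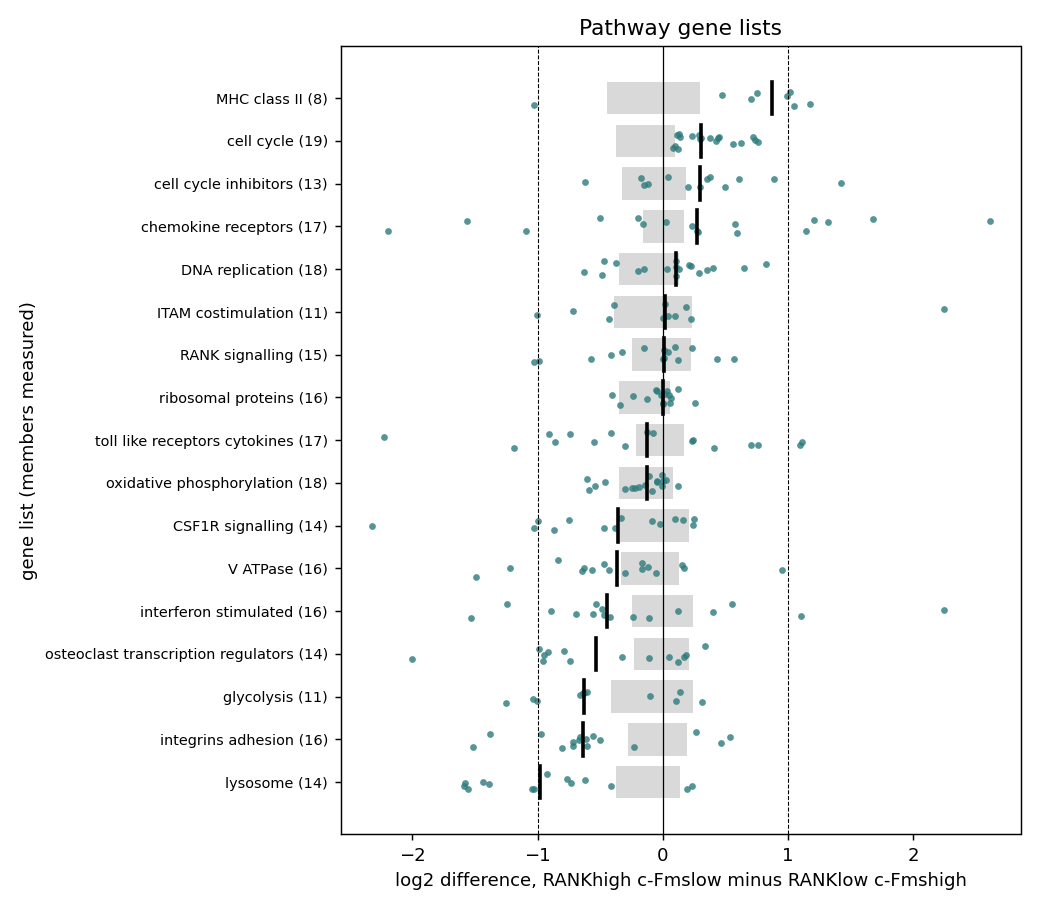
Log2 difference (x axis) of each measured member (points, spread vertically to separate them) of the pathway gene lists (y axis), with list medians (black bars), the central 95% of matched random list medians (grey boxes) and 2-fold (dashed lines). Lysosome genes lie furthest to the left (median -0.98) and MHC class II genes furthest to the right (median 0.87), and RANK signalling genes centre near 0 (median 0.01).

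Lists kept as controls, and the pathway lists of ribosomal protein and oxidative phosphorylation genes, had medians inside the central 95% of random lists matched on level. Immediate early and stress, housekeeping and oxidative phosphorylation genes lay outside it when the random lists were not matched. Ribosomal protein genes had a median of 0.00 and 0 of 16 reached 2-fold, with Rplp1 (-0.41) the furthest from 0. Housekeeping genes had a median of -0.28 (percentile 13.5), with 10 of 11 members below 0. Oxidative phosphorylation genes had a median of -0.13 (percentile 44.3), with 15 of 18 members below 0. In both lists 0 members reached 2-fold. Furthest from 0 were Pgk1 (-0.66), which is also in the glycolysis list, and Atp5a1 (-0.61). Immediate early and stress genes, which cell handling can induce, had a median of 0.19 (percentile 96.7); of 17 members 3 were at least 2-fold higher and 1 at least 2-fold lower. In that list Egr1 (2.54-fold), Ier3 (2.11-fold) and Fosb (2.02-fold) were higher and Atf3 (2.32-fold) was lower on the RANKhigh array. Of the 38 lists, 15 lay above the central 95% of random lists and 9 below it.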

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

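No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Under median centring, quantile normalization, loess and the highest probe set per gene, the named genes (160 genes) kept their sign, with a largest move of 0.22, and the sort markers moved by at most 0.07. List medians moved by at most 0.13 under these settings, and 4 changed sign (macrophage, RANK signalling, ITAM costimulation, ribosomal proteins), none further than 0.015 from 0 in the main setting. Of the 12 genes leading in each direction, 11 or 12 were shared under each of these settings. The counts of genes apart stayed within 1.5 times under all scalings and level filters. They were 83 and 52 (RANKhigh and c-Fmshigh array higher) at 4-fold and 1168 and 1371 at 1.5-fold, which follows from the thresholds. The share of those calls higher on the RANKhigh array was 50.5% at 2-fold, 61.5% at 4-fold and 46.0% at 1.5-fold, and 47.8% to 53.8% under the scalings at 2-fold. Taking list means in place of medians gave -1.34 for monocyte, 1.48 for neutrophil, 2.10 for eosinophil, 1.02 for basophil and mast cell, 0.66 for T cell, -0.38 for dendritic cell, -0.18 for macrophage, 0.26 for osteoclast, -0.13 for RANK signalling, 0.64 for MHC class II and -0.17 for interferon-stimulated genes. In the osteoclast list Car2 (2.00), Mmp9 (1.88) and Acp5 (1.535) lay far above the 12 members within 2-fold, which raised the mean. The other lists were not examined in this way. Restricting lists to members above the level filter gave 1.56 for basophil and mast cell, 1.01 for NK cell, 0.67 for T cell, 0.69 for megakaryocyte and platelet, 0.38 for stem and early progenitor, 0.20 for endothelial, 0.12 for osteoclast and -0.27 for Toll-like receptors and cytokines. The restriction to members above the receptor 95th percentile, chosen after seeing the data, gave 1.02 for basophil and mast cell, -0.67 for dendritic cell, and again 1.01 for NK cell, 0.67 for T cell, 0.69 for megakaryocyte and platelet, 0.38 for stem and early progenitor and -0.27 for Toll-like receptors and cytokines. Low signal over background limits lists with many members near the receptor genes, such as NK cell (6 of 12 members above their 95th percentile) and osteoblast and stromal (6 of 13 members). Values floored at that percentile on each array, also chosen after seeing the data, gave 447 and 441 genes, and 11 and 12 of the 12 leading genes were shared. With random lists not matched on level, 4 further lists left the central range: plasma cell (percentile 98.59), immediate early and stress (99.14), oxidative phosphorylation (2.29) and housekeeping (0.28). Leaving Csf1r out of its signalling list, also chosen after seeing the data, moved it inside the range (percentile 3.56).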

Other observations

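The tests below were chosen after the patterns they concern were seen. For the progenitor gene test, the genes and bounds were fixed before the values of those genes were seen. The bound of the background test of Tnfrsf11a was written before its outcome was known, but the receptor genes as a guide were chosen after the data had been seen. The neutrophil list held a contrast between stages of granule formation. The granule gene groups named here were formed after their values were seen, so their medians describe the contrast and do not test it. Genes of the early (primary) granules did not share the excess on the RANKhigh array: Mpo, myeloperoxidase, stood at 3026 against 4434, Ctsg at 1056 against 1567, Prtn3 at 466 against 643 and Elane at 873 against 716, with a median log2 difference of -0.51. Genes of the later granules, Ltf (5.50-fold), Camp (5.68-fold), Ngp (2.83-fold), Lcn2 (7.43-fold) and Mmp8 (1.44-fold), had a median of 2.46. One hypothesis is that early granulocyte and monocyte progenitors, which express primary granule genes, fell into the c-Fmshigh gate. Progenitor genes fixed before their values were seen gave no answer: their median difference was -0.15, between the bounds of -0.5 and 0 set beforehand. Members went both ways, with Tifab (4.36-fold) and Mgst1 (2.34-fold) lower and Dach1 (2.07-fold) higher on the RANKhigh array.

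Genes of the Y chromosome were expressed alike on both arrays, with Eif2s3y at 766 against 724, Kdm5d at 262 against 256 and Uty at 256 against 304, whereas Xist was at 40.2 against 44.9, in the range of the receptor genes. Olfr419, an olfactory receptor gene and so outside the naming rule, stood at 596 on the RANKhigh array against 104 (5.75-fold), and was chosen after its value was seen. Without a level filter 2 of the 1189 receptor genes were at least 2-fold apart. Among 5430 probe sets with no gene in the annotation table, 2113 passed the level filter, of which 78 were at least 2-fold higher on the RANKhigh array and 62 on the c-Fmshigh array. Among 1605 probe sets naming several genes, the corresponding counts were 34 and 18.

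The transcript of RANK was not higher in the cells sorted for high RANK. Swapped labels are argued against by Csf1r, with a log2 difference of -2.33 in the direction of its label. That value had been seen when the bound of this test was written. Both Tnfrsf11a intensities (104 and 119) lie above the 95th percentile of the receptor genes, 82.6, which speaks only weakly against a probe set at background. Of 19935 genes, 12102 reached that percentile on at least 1 array, so passing it does not show detection. The margin is small, since 2.44% of receptor genes on the RANKhigh array and 1.09% on the c-Fmshigh array exceeded Tnfrsf11a, and a compressed difference at this level stays open. Surface protein that does not follow the transcript, and antibody bound for other reasons, were not tested.

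Markers of several blood lineages that do not occur in a single cell type were higher on the RANKhigh array. Normalization between arrays was examined through median centring, quantile normalization and the trend of the difference on level. After removal of that trend by loess, the mean of the erythroid, early B, mature B and eosinophil medians was 1.85. These 4 lists were chosen after their medians were seen, and no list median moved by more than 0.13 under the alternative scalings. The values argue against a trend on level as the source. Effects of normalization that these scalings do not reach were not tested. A smaller share of monocytic cells with the other lineages in fixed proportion would raise the markers of all of them alike. This was examined over members whose higher value reached an intensity of 245. The medians of the 10 non-monocytic lists with at least 3 such members spanned 3.19. Of the shuffles of the same members among lists of the same sizes, 0.78% spanned as much. Without the eosinophil list the span was 1.63, which 21.0% of shuffles reached. The eosinophil median was 3.57 over its 5 members in this set, against 1.86 over all 8 measured members. The set was taken on the higher of the 2 values, so a large excess on 1 array can itself bring a gene in. The shuffles therefore do not decide this explanation, for the eosinophil list or for the other lineages, and it stays open. The design gives the sort gate itself as the biological difference, and these arrays hold no information on which of the mixed cells carried RANK.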
